A study of Mus musculus with 6 samples.

How the data were processed

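Total liver RNA of Fra-1hep mice (hepatocyte-restricted overexpression of Fra-1, C57BL/6J) and of a wild-type pool was compared on 6 Agilent SurePrint mouse arrays in 2 colours. Per the labels, the mice were 26 to 28 weeks old, RNA had an integrity score above 7.8, and 100 ng was amplified and labelled. The 5 single mice were in Cy5 and the pool of 5 wild-type mice in Cy3, and the sixth array held the wild-type pool in Cy5 and a Fra-1hep pool in Cy3. The series design text speaks of 6 single mice, while the sample labels give 5 and a dye-swapped array of pools; the labels were followed. The Fra-1hep pool was not counted as a further mouse.

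The authors extracted the images with Agilent Feature Extraction (10.7 in the submitters' processing notes, 10.7.3.1 per the file headers). The deposited scanner files hold, for each spot and channel, the median spot and background signal as intensity, with no normalization, and a processed signal that was background-subtracted, spatially detrended and dye-normalised. They also hold the log ratio of the processed signals in log10 units, per the file headers, and marks for spots above background, saturated or uneven. The authors' deposited series table holds log2 ratios of Cy5 over Cy3 processed signal, with the dye-swapped array turned to Fra-1hep over wild type. Each column was checked against its array, and the median absolute difference was at most 1.75e-07. The correlation was 0.9995 in mouse 5 and higher in the other mice, so some probes differ. The columns of that table are not centred, with medians from -0.18 to 0.06.

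Starting from the scanner files, background was corrected with normexp (offset 50) in limma 3.58.1 under R 4.3.3, with the data.table package (version 1.17.8). The median signals were used because the files hold no mean signals. Ratios were normalised within each array by loess, with control spots and spots marked as outliers (190 to 301 per array) given weight 0, and replicate spots of a probe were averaged. Median signals were 90.5 to 114 in red and 46 to 58 in green, and 0 spots were saturated. The offset pulls ratios of dim probes towards 0.

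Probes were named from the accession column of the files, matched to the current names of the mouse GRCm38.p6 RefSeq gene list. Of 55681 probes, 26056 had 1 symbol. The other 29625 had none or more than 1, count as without a symbol and kept the name in that column. The arrays were designed on an earlier genome build, so that list served for names only and no positions are given. A gene was represented by its brightest probe. It was tested if well above background in the Fra-1hep channel on at least 3 of the 5 mouse arrays or in the wild-type channel on at least 3 of the 6 arrays, which kept 30110 probes and 22848 genes (13955 with a symbol). Of 642 changed genes with several probes, 5 had a probe that changed in the other direction. Where a gene was not well above background on any array of a group, as for 11 changed genes in Fra-1hep and 68 in wild type, only a bound holds. It sets the mean of the bright group against the higher, per array, of the dim signal and the lowest signal among probes above background.

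Mice were compared before averaging. The arrays of mice 2 and 3 differed typically by as much as replicate spots do, with 3 genes over 2-fold apart, and were averaged, leaving 4 Fra-1hep samples. For each gene, limma (lmFit and eBayes) fitted log2 of Cy5 over Cy3 with a genotype coefficient (1 on mouse arrays, -1 on the dye-swapped array) and a constant for dye, tested 2-sided against 0 with 3 residual degrees of freedom and 4.67 prior degrees of freedom. In this design the dye-swapped array carries as much weight in the genotype estimate as all mouse arrays together, and the spread comes from the mice. The error of the dye-swapped array itself is not estimated. The wild-type pool is 1 sample. P values were adjusted by Benjamini-Hochberg, and an adjusted p under 0.05 counts as changed. The smallest groups allow no count of other splits of the samples, since only 1 control sample exists.

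The tests, the gene lists, the rule for named genes and all alternatives but those with 5 separate mouse arrays were fixed before the data were examined, while averaging mice 2 and 3 was decided after. The 38 lists covered AP-1 subunits, AP-1 targets in other tissues, PPARγ and lipid droplets, lipid, bile acid, glucose and xenobiotic metabolism, glutathione and NRF2, acute phase, cytokines, interferon, complement, extracellular matrix, cell cycle, p53, ER stress, immediate early genes, the circadian clock, the respiratory chain, zonation, sex bias, sex chromosomes, oncofetal genes, and markers of hepatocytes, cholangiocytes, stellate, endothelial, macrophage, T and NK, B, neutrophil and red blood cells, adipose tissue and pancreas. Lists came from textbook knowledge of the liver, and some share genes. The lipid droplet list was chosen knowing that this laboratory has studied lipid metabolism in mice with altered hepatic AP-1. Each was tested with camera against all other genes at a preset correlation of 0.01, again with an estimated correlation, and with fry, with adjustment over the lists. Members were also adjusted over the list alone. The adipose list had 1 tested member and no list test, and 24 genes with a missing spot were left out of the list tests.

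Named were Fosl1, the 12 genes with the largest rise and the 12 with the largest fall among those with a symbol that changed in the same direction on all 6 arrays, and from each list up to 4 changed members with the smallest p (up to 2 as values where 0 changed). All members of the AP-1 and lipid droplet lists could be named. Outside this rule, Pdk4, Acox2, Cyp3a25, Gstp1, Gsta1, Gsta4, Gclc, Mt1, Fgb, Sparc, Pdgfrb, Trem2, Vwf, Apoa1, Gls2, Rrm2, Dnajb9, C6, Csf3r, Psmb9, Saa1, Saa2 and Cish were chosen after their values were seen, most because they were the few members of a list with a given outcome. Some genes that this rule names are not reported here.

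The alternatives were no dye term (mouse arrays alone, or the dye-swapped ratio turned and averaged in), no background correction, an offset of 10, Feature Extraction log ratios, the authors' series table, median centring, Aquantile, no filter, a strict filter, the mean over probes, an intensity trend with robust variance, slide as a random block, a single slide, a fold threshold of 1.5, an adjusted p under 0.01, and leaving out each mouse. The single slide held mice 3 and 4 and the dye-swapped array, so that fit rests on these mice alone and has fewer residual degrees of freedom. Leaving out mouse 2 or 3 kept the other array in place of their mean, so no fit left out the sample that they form. Counting the 5 mouse arrays separately, as first planned, became an alternative after mice 2 and 3 were found to be alike. It was also used for the slide block, since these mice lay on different slides of the 3. Figures were drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

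The steps were tested on simulated data of the same design with 22848 genes, of which 200 were changed. Of planted 1.5-fold changes 52 of 80 (65%) were recovered, of 2-fold changes 56 of 60 (93.3%) and of 4-fold changes 60 of 60, with 0 calls among unchanged genes and 0 in the wrong direction. Estimated log2 changes were 0.866, 0.777 and 0.819 of the true ones. A planted list gave an adjusted p of 2.4e-73 with camera and 0.0100 with an estimated correlation, and 0 unchanged lists were called. The simulated genes varied independently, and the wild-type pool had no deviation of its own. The dye-swapped array was simulated with a smaller spread than a mouse array, while the fit treats them alike. On the real arrays it lay further from every mouse than the mice lay from each other, a distance that includes any dye effect. These counts therefore cannot show false calls that arise from correlated genes, from a peculiar pool or from a deviating dye-swapped array.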

Results

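Liver gene expression was measured on 6 Agilent mouse arrays in 2 colours, each with 62976 spots. The animals were Fra-1hep mice, in which hepatocytes overexpress Fra-1, the AP-1 transcription factor subunit encoded by Fosl1, on the C57BL/6J strain and aged 26 to 28 weeks. On 5 arrays, Cy5-labelled RNA of a single Fra-1hep mouse was set against a Cy3-labelled pool of liver RNA from 5 chow-fed wild-type mice. On the sixth array the dyes were exchanged, with a Fra-1hep pool in Cy3 and the wild-type pool in Cy5. Of 55681 probes, 48.5 to 58.9% per array were well above background in the Fra-1hep channel and 45.0 to 50.7% in the wild-type channel, and 0 spots were saturated. The share followed the dye: Cy5 had the larger one on every array, also on the dye-swapped array (wild type 50.7%, Fra-1hep 48.5%). The number of arrays limits the precision of every value given here.

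The arrays of mice 2 and 3, which lay on different slides, differed typically by as much as replicate spots of a probe do (1.03 times). Of the genes compared, 3 were over 2-fold apart, all without a symbol. Furthest apart was the transcript ENSMUST00000082402 (log2 ratio 0.42 in mouse 2 and 2.87 in mouse 3), chosen here after its values were seen. Over 8945 brighter genes, the spread of their difference (scaled median absolute deviation of log2 ratios) was 0.107, against 0.104 expected from 142 probes spotted in replicate. For the 9 other pairs of mice this spread was 0.166 to 0.226, which was 1.85 to 2.39 times the noise expected for each pair. The 2 arrays were therefore averaged and counted as 1 sample, so that n = 4 Fra-1hep samples in the values below unless given otherwise. The dye-swapped array, turned to the same direction, differed from the mouse arrays by 2.59 to 3.47 times the noise. That difference includes any dye effect, and the error of this array does not enter the SE values below. Across the 18264 genes well above background in both channels on all arrays, the median SD between the 5 mouse arrays was 0.123 on the log2 scale. Cish, a STAT-induced suppressor of cytokine signalling chosen here after its values were seen, had the largest SD over the 4 counted samples among those with a symbol (1.94), with log2 ratios from -2.71 in mouse 1 to 2.01 in mouse 4.

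**Figure D1:**
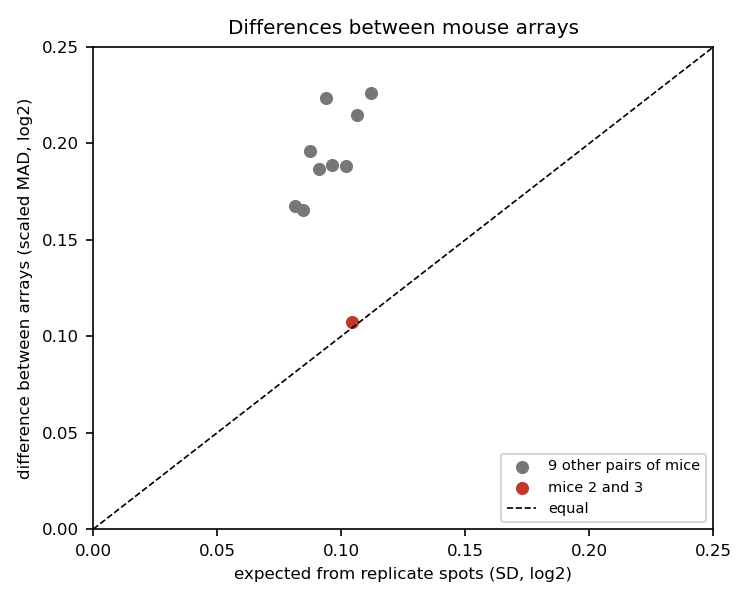
Each point is a pair of mouse arrays, with the spread of their difference in log2 ratio (vertical axis) against the spread expected from replicate spots (horizontal axis), and the dashed line marks equal values. Mice 2 and 3 lie at 0.107 against 0.104, and the 9 other pairs lie at 0.166 to 0.226.

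The overexpressed gene itself was not measurable. The only Fosl1 probe (A_51_P308796) was well above background on 0 of 6 arrays in either channel, and its log2 ratio was -0.07 (SE 0.06, n = 4), with an adjusted p of 0.614 in a fit without the filter on dim probes. Its signal in the Fra-1hep channel ranked between 88.6% and 99.7% of the negative control spots of the same array. The position of the probe in the transcript is not given in the sources used here, so Fosl1 does not check the labels, and the mice are named Fra-1hep from the labels alone.

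The main comparison asked which liver transcripts differ between Fra-1hep mice and wild type. The largest rise was in Asns (NM_012055), encoding asparagine synthetase, which was 42.9-fold higher in Fra-1hep liver (log2 5.42, SE 0.14, n = 4, adjusted p = 1.83e-06). The largest fall was in Cyp4a14 (NM_007822), a fatty acid omega-hydroxylase and classical PPARα target, which was 64.5-fold lower (log2 -6.01, SE 0.19, adjusted p = 4.95e-06). Of 11 neutrophil markers 10 rose, S100a9 by 11.5-fold, while 18 of 19 interferon response genes, 14 of 20 macrophage markers, 13 of 27 genes of fatty acid oxidation and PPARα and 9 of 18 cytokines and chemokines fell. Each of these 5 lists passed with camera at the preset correlation but not with an estimated correlation (adjusted p = 0.442). Genes of lipid droplets moved in both directions, with Vldlr, Cidec and Lpl higher and Plin2, Fitm1 and Pparg lower.

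Of 22848 genes tested, 2851 (12.5%) changed at an adjusted p under 0.05, with 1364 higher and 1487 lower in Fra-1hep liver. With a symbol were 13955 of the tested genes and 2216 of the changed ones. The other 8893 were counted by accession or probe name and may repeat a gene. At least 1.5-fold changes were seen for 808 of the 2851 (379 higher, 429 lower) and at least 2-fold changes for 272 (152 higher, 120 lower). All 6 arrays had the same direction for 2648 of the 2851 genes. With median centring in place of loess, 74.8% of the changed genes were higher (2467 higher, 833 lower), against 47.8% in the analysis given here, and the median log2 ratio of all genes was 0.08 instead of 0.01.

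Among the 12 genes that rose most, Lrtm2 (log2 4.17, SE 0.06), Cela1 (3.52, SE 0.09), Inava (3.34, SE 0.08), Gipc2 (3.09, SE 0.10) and Lysmd2 (3.05, SE 0.13) varied little between mice. Cela1 encodes an elastase-type protease. The wild-type signal of Lrtm2 was well above background on 1 of 6 arrays. The granulocyte genes S100a9 (3.53, SE 0.40), Mpo (3.48, SE 0.56), S100a8 (3.48, SE 0.41) and Camp (3.36, SE 0.47) rose with a wider spread, as did Igfbp1 (3.07, SE 0.36), a secreted binding protein of insulin-like growth factors. Tff3, a mucosal trefoil peptide, was 9.61-fold higher (log2 3.27, SE 0.29). Adjusted p values of these 12 genes lay between 7.83e-08 for Lrtm2 and 0.00759 for Mpo. Each gene was higher on all 6 arrays, which the selection required.

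The 12 genes that fell most were led, after Cyp4a14, by Dmbt1 (log2 -3.34, SE 0.07), a secreted scavenger-receptor glycoprotein, and by Cfd (-3.28, SE 0.07), which encodes complement factor D or adipsin. Cfd was well above background on 0 of 6 arrays in the Fra-1hep channel, so it was at least 8.96-fold lower. The steroid-metabolising enzymes Hsd17b6 (-3.27, SE 0.16) and Hsd3b5 (-3.14, SE 0.21) fell, as did the kynurenine aminotransferase Kyat3 (-3.07, SE 0.49). Cyp4a31 (-2.98, SE 0.34) and Cyp4a10 (-2.97, SE 0.34) are close paralogs of Cyp4a14, and signal shared between their probes was not measured. Further probes of Cyp4a10 were at -3.21 and -2.05. Also lower were Serpina4-ps1 (-2.86, SE 0.28), the organic anion transporter Slco1a1 (-2.73, SE 0.33), the iron hormone hepcidin, Hamp (-2.50, SE 0.48), and liver fatty acid-binding protein, Fabp1 (-2.50, SE 0.31). Their adjusted p values lay between 7.82e-07 for Dmbt1 and 0.015 for Hamp. All 12 were lower on all 6 arrays, again by the selection.

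**Figure D2:**
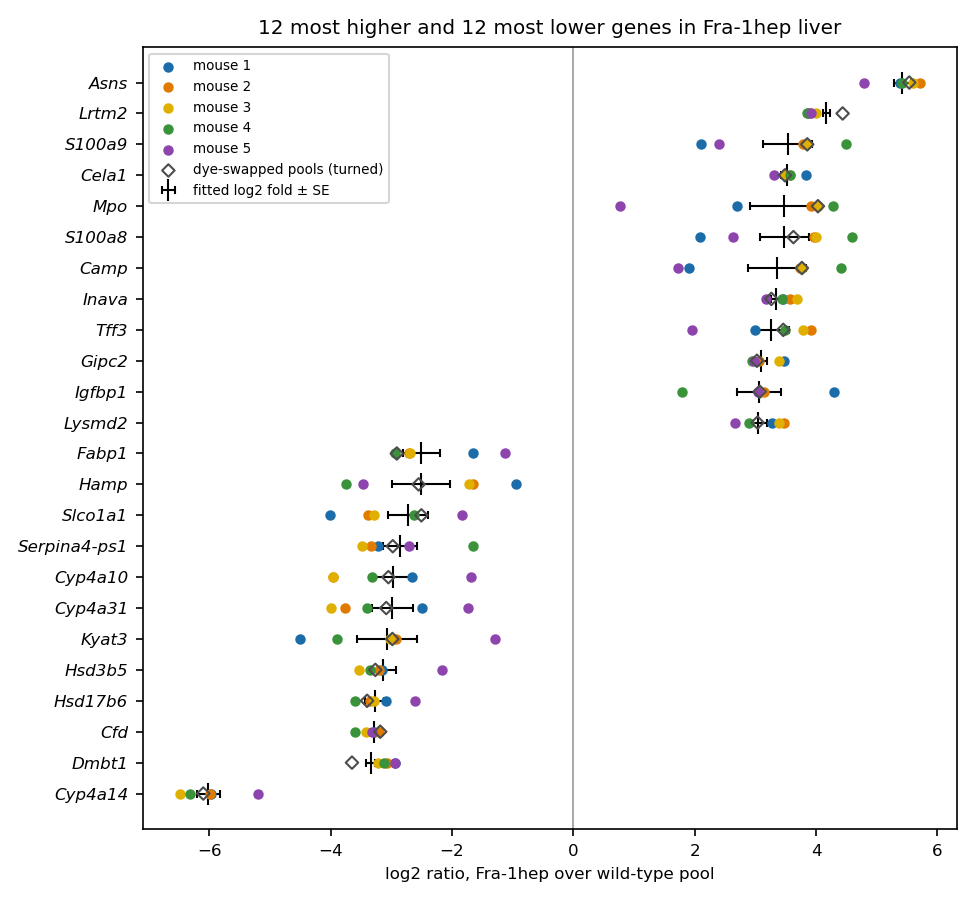
Log2 ratio of Fra-1hep liver over the wild-type pool for the 12 genes that rose most and the 12 that fell most, with a point for each mouse, a diamond for the dye-swapped pools turned to the same direction, and bars for the fitted value ± SE. Fitted values run from 5.42 for Asns to -6.01 for Cyp4a14. All values of a gene lie on the same side of 0 because the genes were selected for this.

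Changes of AP-1 genes other than Fosl1 ran from -0.62 to 0.56 on the log2 scale. Of 15 tested AP-1 subunits and partners, 1 rose, 5 fell and 9 did not pass the test, and 8 changed when adjusted over the list alone. Mafk rose (log2 0.56, SE 0.08, adjusted p = 0.00381), while Batf3 (-0.62, SE 0.08), Batf (-0.59, SE 0.09), Batf2 (-0.52, SE 0.10), the stress-induced Atf3 (-0.51, SE 0.09) and Maff (-0.24, SE 0.06) fell. Maff no longer passed without mouse 1, 2, 4 or 5 (adjusted p up to 0.0794). The values of Fosl2 (0.28, adjusted p = 0.116), Junb (-0.19, adjusted p = 0.159), Fos (-0.21, adjusted p = 0.239) and Jun (-0.01, adjusted p = 0.975) did not pass. The list as a whole did not pass either (camera adjusted p = 0.0872). Of 9 tested genes named as AP-1 targets in other tissues, 1 rose, the chromatin protein gene Hmga1 (0.32, SE 0.06, on 1 of its 3 probes, the others at 0.11 and 0.07 not passing), and 8 did not pass, while 5 changed adjusted over the list alone (camera adjusted p = 0.947).

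Of 17 PPARγ and lipid droplet genes, 5 rose, 7 fell and 5 did not pass, and 14 changed adjusted over the list alone (7 higher, 7 lower). The receptor and lipase of triglyceride-rich lipoproteins rose: Vldlr was 3.62-fold (log2 1.86, SE 0.23) and Lpl 2.58-fold higher (1.37, SE 0.16). Cidec, which enlarges lipid droplets, was 3.20-fold higher (1.68, SE 0.21). A further probe of each gene gave a smaller rise, 0.93 for Vldlr, 0.82 for Lpl and 1.11 for Cidec. Small rises in Pnpla2 (0.28, SE 0.07) and Plin3 (0.28, SE 0.07) were seen. They did not pass without some of the mice (adjusted p up to 0.0696 without mouse 1 or 4, and up to 0.0832 without mouse 2, 3, 4 or 5). Pparg itself, the adipogenic nuclear receptor, was 2.69-fold lower (-1.43, SE 0.15). The droplet coat genes Plin2 (-1.36, SE 0.09) and Plin4 (-1.28, SE 0.17), the fat storage-inducing genes Fitm1 (-1.64, SE 0.15) and Fitm2 (-0.38, SE 0.09), the lipase inhibitor G0s2 (-0.88, SE 0.14) and Cidea (-0.94, SE 0.06) fell. Cidea was well above background on 1 of 6 arrays in the Fra-1hep channel. Fitm2 did not pass without mouse 3 (adjusted p = 0.0577), a fit in which mouse 2 alone stood for the averaged sample. Cd36 (0.31, adjusted p = 0.0978), Fabp4 (0.49, adjusted p = 0.143), Mogat1 (0.39, adjusted p = 0.184), Plin5 (-0.13, adjusted p = 0.55) and Hilpda (-0.01, adjusted p = 0.974) did not pass. With members in both directions, the list did not pass as a whole (camera adjusted p = 0.460).

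**Figure D3:**
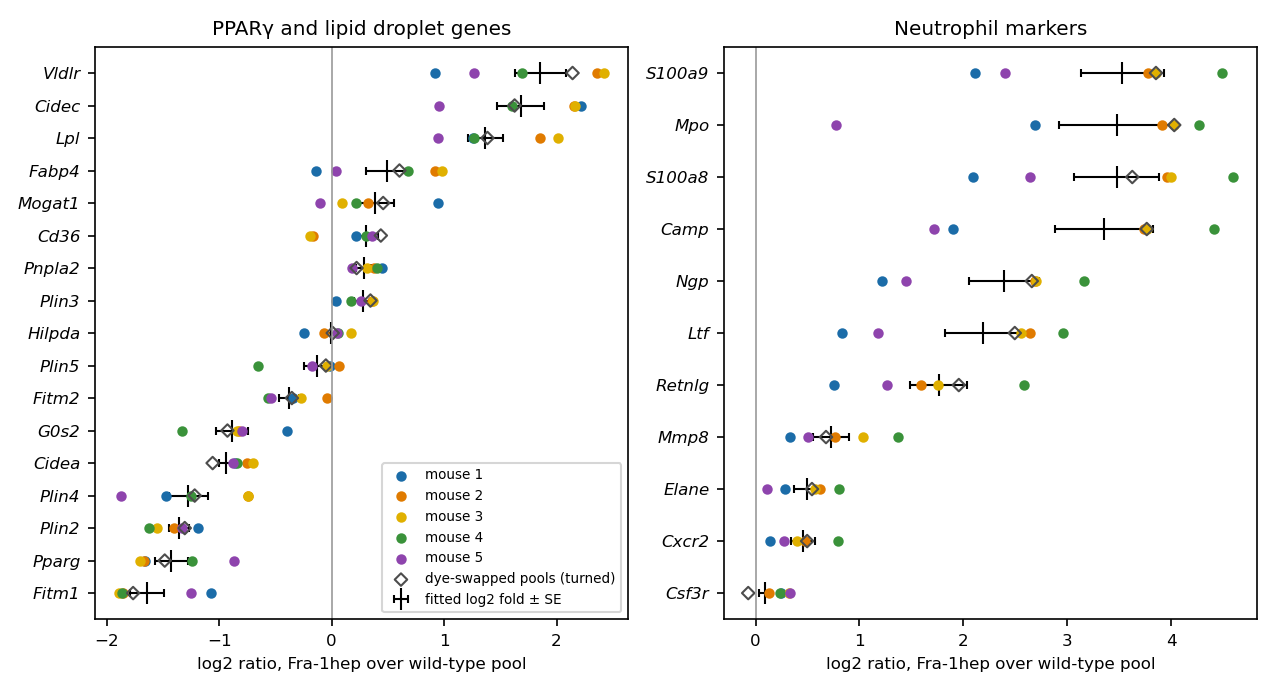
Log2 ratio of Fra-1hep liver over the wild-type pool for the PPARγ and lipid droplet genes (left) and the neutrophil markers (right), with a point for each mouse, a diamond for the dye-swapped pools and bars for the fitted value ± SE. Lipid genes range from 1.86 for Vldlr to -1.64 for Fitm1, and the neutrophil markers spread widely between mice, with Mpo at 0.77 in mouse 5 and 4.27 in mouse 4.

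Genes of fatty acid oxidation and PPARα fell: of 27 tested, 13 were lower and 1 was higher, and 15 were lower and 1 higher adjusted over the list alone (camera adjusted p = 1.06e-07, adjusted p = 0.442 with an estimated correlation). Besides Cyp4a14, Cyp4a10 and Fabp1, they included the pantetheinase Vnn1 (log2 -1.50, SE 0.11) and the fatty aldehyde dehydrogenase Aldh3a2 (-0.98, SE 0.08). The exception was Pdk4 (0.63, adjusted p = 0.0266), a kinase that inhibits pyruvate dehydrogenase. In fatty acid and triglyceride synthesis, 2 of 22 genes fell and 1 rose, and 5 changed adjusted over the list alone. That list shifted lower as a whole (camera adjusted p = 0.0326, adjusted p = 0.714 with an estimated correlation), a call that ended without mouse 1 (adjusted p = 0.0682). Its median was 0.42 in mouse 5, against -0.63 to -0.50 in the other samples. The desaturase Scd2 rose (0.50, SE 0.11), and the elongase Elovl5 (-0.99, SE 0.24) and the desaturase Fads2 (-0.40, SE 0.10) fell, each near the threshold. Scd2 did not pass without mouse 5 (adjusted p = 0.0531), Elovl5 without mouse 1 or 4 (up to 0.0630) or with an intensity trend and robust variance (0.197) and Fads2 without mouse 1, 3 or 4 (up to 0.0729). Of 24 cholesterol synthesis and uptake genes, 1 rose (Mvk, mevalonate kinase, 0.55, SE 0.09) and 3 fell, namely Sc5d (-0.64, SE 0.13), Cyp51 (-0.50, SE 0.12) and Hsd17b7 (-0.33, SE 0.09), which did not pass without mouse 4 (adjusted p = 0.0708). Adjusted over the list alone 9 changed, and the cholesterol list did not pass (camera adjusted p = 0.126), though it did without mouse 5 (adjusted p = 0.0102).

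Neutrophil markers rose: 10 of 11 tested were higher, also 10 adjusted over the list alone, with a median log2 ratio of 2.19 (camera adjusted p = 5.57e-08, adjusted p = 0.442 with an estimated correlation). S100a9 and S100a8, the subunits of calprotectin, were 11.5-fold and 11.1-fold higher, and the granule genes Camp and Ngp were 10.2-fold and 5.26-fold higher (Ngp log2 2.39, SE 0.34), with a further probe of Camp at 2.77. With an intensity trend and robust variance these 4 genes did not pass (adjusted p = 0.0570 for S100a9, 0.0610 for S100a8, 0.0885 for Camp and 0.0787 for Ngp). Csf3r, the receptor of granulocyte colony-stimulating factor, was the member that did not pass (0.09, adjusted p = 0.350). The sample medians of the list ran from 0.83 to 2.96. Of 20 macrophage markers, 14 fell and 1 rose (Trem2, 0.48, adjusted p = 0.0214), and 15 fell and 2 rose adjusted over the list alone (camera adjusted p = 1.74e-06, adjusted p = 0.442 with an estimated correlation). Itgax (-0.94, SE 0.12), the Kupffer cell lectin Clec4f (-0.61, SE 0.10), C1qa (-0.59, SE 0.09) and Adgre1 (-0.58, SE 0.10) were among those that fell.

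T and NK cell markers fell in 7 of 15 cases with 0 higher, and in 13 adjusted over the list alone (camera adjusted p = 2.59e-07, adjusted p = 0.442 with an estimated correlation), as in Gzma (log2 -1.50, SE 0.25, adjusted p = 0.0894 with an intensity trend and robust variance), Cd2 (-0.37, SE 0.07), Gzmb (-0.36, SE 0.06) and Klrd1 (-0.33, SE 0.07). Of 16 endothelial markers, 11 fell and 2 rose, and 13 fell and 2 rose adjusted over the list alone (camera adjusted p = 1.56e-05, adjusted p = 0.442 with an estimated correlation). The sinusoidal lectin Clec4g (-0.95, SE 0.15), Stab1 (-0.44, SE 0.08) and Eng (-0.42, SE 0.07) were lower, and the VEGF receptor Flt1 (0.83, SE 0.10) and Vwf (0.38, adjusted p = 0.0188) were higher. Of 5 red blood cell markers, Alas2 fell (-0.65, SE 0.08) and 4 did not pass, with 1 changed adjusted over the list alone. The red blood cell list had a camera adjusted p of 0.0419 (adjusted p = 0.494 with an estimated correlation), and of 0.0717 without mouse 1.

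Interferon response genes fell together, 18 of 19 over all genes tested and 19 adjusted over the list alone, by a median log2 ratio of -0.58 (camera adjusted p = 1.28e-16, adjusted p = 0.442 with an estimated correlation). The immunity-related GTPase genes Iigp1 (-0.96, SE 0.09) and Irgm1 (-0.82, SE 0.08), and also Ifi27l2a (-0.82, SE 0.07) and Ifit1 (-0.58, SE 0.07), were lower. Psmb9 was the member that did not pass (-0.27, adjusted p = 0.0739). Cytokines and chemokines fell in 9 of 18 cases with 0 higher, while 13 fell and 1 rose adjusted over the list alone (camera adjusted p = 1.4e-06, adjusted p = 0.442 with an estimated correlation). The chemokine genes Cxcl10 (-1.61, SE 0.20), Ccl4 (-1.36, SE 0.11), Ccl3 (-0.88, SE 0.07) and Ccl2 (-0.84, SE 0.12) were lower. Of 27 acute phase protein genes, 14 fell and 3 rose, and 19 fell and 4 rose adjusted over the list alone (camera adjusted p = 3.52e-06, adjusted p = 0.442 with an estimated correlation). Saa3 (-1.89, SE 0.15), Hpx (-0.97, SE 0.10) and Lcn2 (-0.82, SE 0.07) fell, while the metallothioneins Mt2 (2.71, SE 0.28) and Mt1 (2.27, adjusted p = 0.00855) and the fibrinogen gene Fgb (0.88, adjusted p = 0.0199) rose. Fgb depended on the dye term, with ratios of 0.89 to 2.01 on the mouse arrays and 0.13 on the dye-swapped array. With an intensity trend and robust variance Fgb (adjusted p = 0.0805) and Mt1 (adjusted p = 0.116) did not pass. Saa1 and Saa2, chosen after their values were seen, did not pass (-1.85, adjusted p = 0.0755, and -2.36, adjusted p = 0.0521), with mouse 1 at 0.30 and -0.09 and the other mice between -2.05 and -4.05.

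Male-biased liver genes, many of which follow the male pattern of growth hormone release, fell in 8 of 15 cases and rose in 1 (C6, log2 0.46, adjusted p = 0.0125), and 8 fell and 2 rose adjusted over the list alone (camera adjusted p = 1.91e-05, adjusted p = 0.442 with an estimated correlation). Hsd3b5, Elovl3 (-2.02, SE 0.15), and the major urinary protein genes Mup21 (-1.78, SE 0.16) and Mup3 (-1.68, SE 0.20) were lower. Signal shared between these close paralogs was not measured. Of 8 female-biased liver genes, Fmo2 rose (0.51, SE 0.09), Cyp2b9 (-0.61, SE 0.09) and Cyp3a16 (-0.55, SE 0.10) fell and 5 did not pass, with 4 changed adjusted over the list alone (camera adjusted p = 0.363). The Y-linked Ddx3y (0.15, SE 0.06, adjusted p = 0.143) and Uty (-0.08, SE 0.07, adjusted p = 0.491) did not pass, and 0 of the 3 tested sex chromosome genes passed, also adjusted over the list alone (camera adjusted p = 0.855).

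Bile acid synthesis and transport genes fell in 8 of 23 cases and rose in 1, Acox2 (log2 0.31, adjusted p up to 0.0712 without mouse 1 or 4), and 8 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.00613, adjusted p = 0.494 with an estimated correlation). With Slco1a1, the bile salt export pump Abcb11 (-0.73, SE 0.10), Hsd3b7 (-0.72, SE 0.11) and the sterol transporter Abcg5 (-0.51, SE 0.08) were lower. Xenobiotic cytochrome P450 and related genes fell in 6 of 22 cases and rose in 2, and 10 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.000823, adjusted p = 0.494 with an estimated correlation). The receptor CAR, Nr1i3, was lower (-0.65, SE 0.12), and Cyp2c55 (1.14, SE 0.13) and Cyp3a25 (0.43, adjusted p up to 0.0533 without mouse 4) were higher.

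Glucose metabolism genes rose in 6 of 16 cases with 0 lower, while 7 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.0188, adjusted p = 0.494 with an estimated correlation). Pck1, the gluconeogenic phosphoenolpyruvate carboxykinase, was 2.27-fold higher (log2 1.19, SE 0.13), and the insulin receptor substrate Irs2 rose too (0.77, SE 0.09). Of 12 periportal hepatocyte genes, 5 rose and 1 fell, and 7 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0326, adjusted p = 0.442 with an estimated correlation). Besides Pck1, these were the serine dehydratases Sdsl (1.41, SE 0.23, adjusted p = 0.0898 with an intensity trend and robust variance) and Sds (0.90, SE 0.13), Ass1 (0.40, SE 0.09) and Gls2 (0.45, adjusted p up to 0.0720 without mouse 1, 3 or 4), and Hsd17b13 fell (-0.51, SE 0.07). Its other probe did not (0.02, adjusted p = 0.896). Pericentral hepatocyte genes fell in 4 of 11 cases with 0 higher, while 4 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.0326, adjusted p = 0.494 with an estimated correlation). They were the glutamate transporter Slc1a2 (-0.86, SE 0.12, further probes at -0.76 and -0.42), glutamine synthetase, Glul (-0.85, SE 0.21, adjusted p up to 0.0631 without mouse 4 or 5, and 0.180 with an intensity trend and robust variance), Oat (-0.41, SE 0.09) and Ahr (-0.37, SE 0.10, adjusted p up to 0.0626 without mouse 1, 4 or 5).

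General hepatocyte markers did not shift as a list: 3 of 21 rose and 3 fell, and 13 changed adjusted over the list alone (camera adjusted p = 0.649). Ass1 was among those that were higher, and Alb (log2 -0.65, SE 0.10), Asgr2 (-0.36, SE 0.06) and Apoa1 (-0.34, adjusted p = 0.0261) were lower. Alb depended on the dye term: its ratios were -0.46 to 0.07 on the mouse arrays and -1.08 on the dye-swapped array. Cholangiocyte and progenitor markers rose in 8 of 16 cases and fell in 1, Dmbt1, and 12 rose and 1 fell adjusted over the list alone (camera adjusted p = 1.91e-05, adjusted p = 0.442 with an estimated correlation). Osteopontin, Spp1 (1.04, SE 0.09), Prom1 (0.66, SE 0.08) and Cldn7 (0.62, SE 0.07) were higher. Of 8 oncofetal and tumour-associated liver genes, Tff3 and Spink1 (1.33, SE 0.23, adjusted p = 0.0885 with an intensity trend and robust variance) rose and 6 did not pass, with 4 higher and 1 lower adjusted over the list alone (camera adjusted p = 0.0168, adjusted p = 0.442 with an estimated correlation).

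Cell cycle genes fell in 7 of 22 cases and rose in 1 (Rrm2, log2 0.28, adjusted p = 0.0169), and 7 fell and 2 rose adjusted over the list alone (camera adjusted p = 0.000823, adjusted p = 0.494 with an estimated correlation). Cyclin D1, Ccnd1, was 2.30-fold lower (-1.20, SE 0.11), and Mcm3 (-0.54, SE 0.06), E2f1 (-0.52, SE 0.06) and Mcm4 (-0.44, SE 0.06), which act in DNA replication or its control, fell. Among 15 p53 targets, 4 fell with 0 higher, and 5 fell adjusted over the list alone (camera adjusted p = 0.0378, adjusted p = 0.494 with an estimated correlation), a list call that ended without mouse 1 (adjusted p = 0.0702) or mouse 5 (adjusted p = 0.0620). They were the stress cytokine gene Gdf15 (-1.13, SE 0.13), Gadd45a (-0.61, SE 0.14, adjusted p = 0.0542 without mouse 1), Phlda3 (-0.50, SE 0.07) and Pmaip1 (-0.46, SE 0.08).

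**Figure D4:**
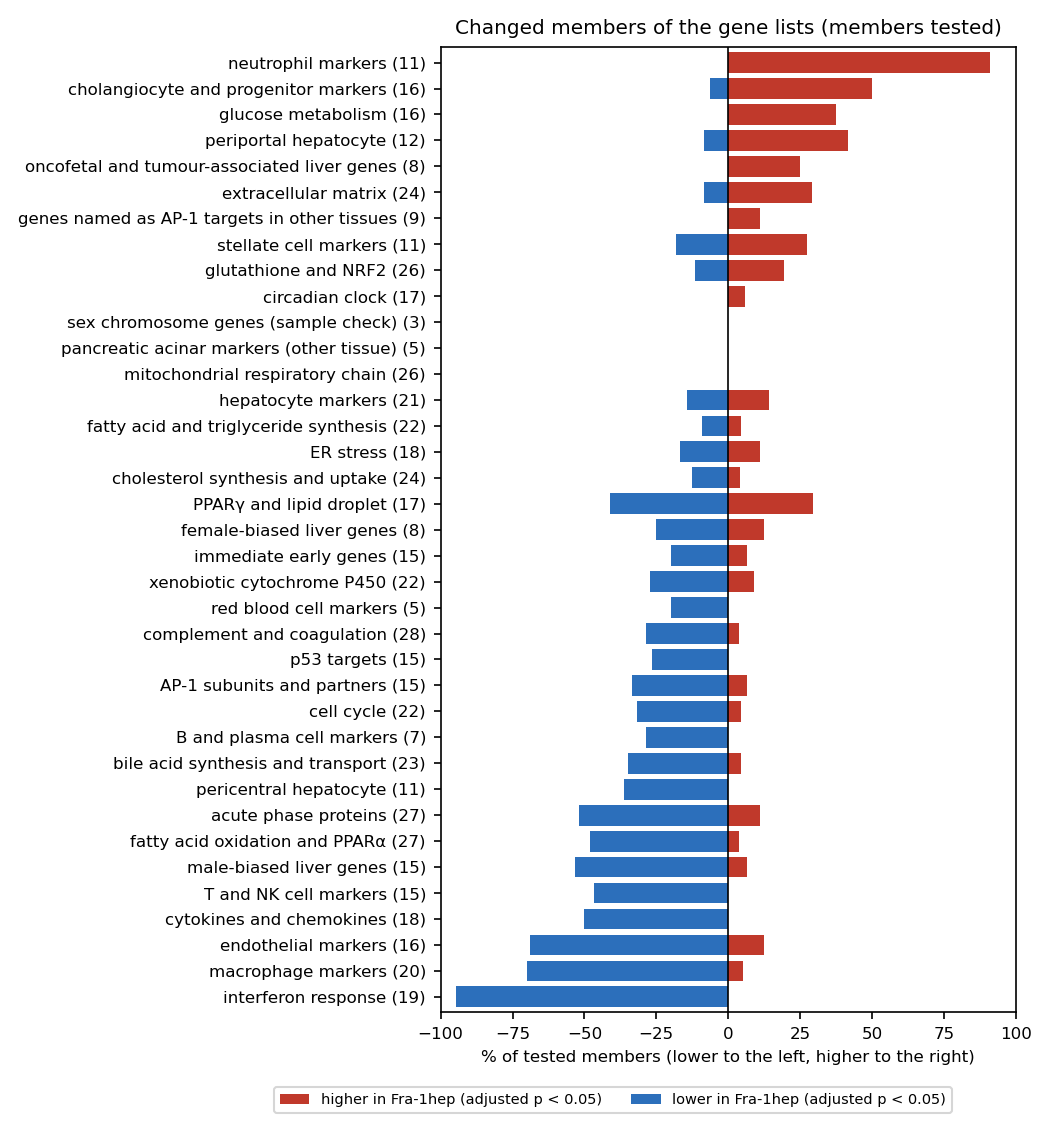
Share of the tested members of each gene list (their number in brackets) that changed in Fra-1hep liver at an adjusted p under 0.05. Bars to the right give those that were higher and bars to the left those that were lower, in %. The adipose list, with 1 tested member, is left out. Neutrophil markers lie at the upper end, with 10 of 11 higher, and interferon response genes at the lower end, with 18 of 19 lower.

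Of 37 lists tested with camera at the preset correlation, 21 passed (5 higher, 16 lower), and 4 passed with fry. With an estimated correlation 0 passed, where the lowest adjusted p was 0.442 and 3 lists had an unadjusted p under 0.05. That version of camera uses only the 3 residual degrees of freedom, which weakens it apart from any correlation between genes. The control was a single pool on every array, so the test leaves out the spread between wild-type mice, and a rise or fall cannot be separated from a peculiarity of that pool. With an intensity trend and robust variance, 13 of the 24 genes named by size still passed, and S100a9, Mpo, S100a8, Camp, Igfbp1, Kyat3, Cyp4a31, Cyp4a10, Slco1a1, Hamp and Fabp1 did not (adjusted p 0.0538 to 0.154). With Feature Extraction log ratios, 56 of the 158 named genes that changed did not pass, Kyat3 and Hamp among them. The count of changed genes was 3460 with the 5 mouse arrays counted separately and 3434 with slide as a random block in addition. It was 3026 on the slide that held both dye orientations, a fit of only mice 3 and 4 and the dye-swapped array. A gene-specific dye effect was found for 205 genes.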

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

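The tests of explanations in this part were chosen after the results were seen; the search for single samples that stand apart was fixed before.

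For 182 named genes and 38 list medians, the 4 Fra-1hep samples were searched for 1 sample far from the other 3 (Dixon's ratio), which chance alone gives in about 1 in 20. This was so for 11 genes (6.04%) and 2 list medians. Mouse 5 stood apart in 5 of the 11 genes, mouse 1 in 3, mouse 4 in 2, and mice 2 and 3 in 1. In mouse 5, Elovl5 was at a log2 ratio of 0.10 while the others were at -1.33 to -1.11, and the median of the fatty acid and triglyceride synthesis list was 0.42 against -0.63 to -0.50. Mouse 5 also had Saa3 at -1.35 (others -2.16 to -2.10), Irgm1 at -0.72 (others -1.09 to -1.05), Mafk at 0.32 (others 0.60 to 0.65) and Gclc at -0.57 (others -0.45 to -0.42). Mouse 1 had Fgb at 0.89 (others 1.84 to 1.93), Pdia6 at -0.20 (others -0.60 to -0.54) and Hilpda at -0.24 (others 0.05 to 0.06). Mouse 4 had Gzmb at -0.46 (others -0.35 to -0.33). Cfd, the only tested member of the adipose list, was at -3.59 in mouse 4 (others -3.32 to -3.28), but was well above background on 0 arrays in the Fra-1hep channel, so this difference is one of background signal and shows nothing about expression in mouse 4. The mean of mice 2 and 3 had Ahr at -0.77 (others -0.36 to -0.30).

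Mice 2 and 3 gave nearly the same profile. A shared slide is excluded as the reason, since they lay on different slides and the other pair of mice on 1 slide that differed least still differed by 2.02 times the noise of replicate spots. The difference between mice 2 and 3 was 1.03 times that noise, which is consistent with the same RNA on both arrays, although 3 genes were over 2-fold apart, against 62 to 103 in the other pairs. Littermates or mice of very like state stay open, untested, although the 9 other pairs differed by at least 1.85 times the noise.

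Neutrophil markers were higher in every Fra-1hep sample, with sample medians of 0.83 to 2.96. Whole blood left in the liver would bring red blood cell transcripts too, but their highest sample median was 0.18, below the lowest neutrophil median, which argues against it; blood rich in neutrophils stays open. A smaller share of hepatocytes would raise macrophage and endothelial markers alike, and their highest sample median was -0.21. Whether the wild-type pool was low in neutrophils cannot be told apart from a rise in Fra-1hep, because all values, down to 0.83, refer to that 1 pool. An effect of the genotype on neutrophils or their precursors in liver stays open as an untested hypothesis.

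Of 15 male-biased genes, 8 were lower in Fra-1hep liver, 1 was higher and 6 did not pass. The list passed with camera at the preset correlation, but not with an estimated correlation (adjusted p = 0.442) or with fry (adjusted p = 0.0579). Female livers among the Fra-1hep mice would lack Y-linked transcripts, but the lowest Ddx3y ratio of the 5 mouse arrays was 0.13. A general fall of hepatocyte transcripts cannot be judged, because the loess centres the ratios of each array near 0 and would remove much of it. The male-biased genes fell beyond the hepatocyte markers, with sample medians of -0.23 or lower against a lowest hepatocyte median of -0.0310. A change of growth hormone signalling or an effect of the genotype stays open and was not tested, as does a peculiarity of the wild-type pool.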

How the results depend on the processing

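Averaging mice 2 and 3, and so the alternative that counts the 5 mouse arrays separately, alone and with slide as a block, was chosen after the data were seen; the others were planned. No named changed gene and no list call turned direction under any alternative. The cause of each change below was not tested, unless given. Adjusted p values of lists are of camera unless given.

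The 2851 changed genes became 6099 (3461 higher, 2638 lower) with mouse arrays alone and no dye term, of which 2579 were the same genes, and 4787 (2483 higher, 2304 lower) with the dye-swapped ratio averaged in. Without the dye term, any dye bias stays in the estimate, and 2840 of the 2851 kept their direction with mouse arrays alone. With Feature Extraction log ratios 1546 changed (754 higher, 792 lower, with 1341 of the same genes), and the dye coefficient passed for 2 genes instead of 205. The authors' series table gave 1545 (754 higher, 791 lower). Median centring gave 2467 higher and 833 lower. By construction, a fold of at least 1.5 left 808 and an adjusted p under 0.01 left 1074. Other settings gave 2315 to 3460, and leaving out a mouse 2319 to 2719, within 1.5 times the count.

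Fosl1 stayed at log2 -0.18 to -0.04 over 18 alternatives (adjusted p 0.476 or higher) and has no value under the filters on dim probes. Of the 24 genes named by size, 13 passed with an intensity trend and robust variance, with the same fold. Elovl5 (0.197), Gzma (0.0894), Ngp (0.0787), Glul (0.180), Sdsl (0.0898), Spink1 (0.0885), Gsta1 (0.146), Mt1 (0.116) and Fgb (0.0805) also did not pass there (adjusted p of the gene). Fgb was at 1.63 with mouse arrays alone, against 0.88. A further probe did not pass for Hmga1, Hsd17b13, Cd2 (log2 -0.17), Ass1 (0.38), Ahr (-0.14), Hsd17b7 (-0.26) and Dnajb9 (0.25). Of 158 named changed genes, 138 passed there, 102 with Feature Extraction log ratios, 138 with median centring, 138 with an offset of 10, and 138 in every fit without a mouse.

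The 56 named genes that did not pass with Feature Extraction log ratios (adjusted p 0.0516 to 0.139), nor with the series table, include Acox2, Adgre1, Ahr, Apoa1, Asgr2, Ass1, Atf3, C1qa, Calr, Clec4g, Col6a1, Cry2, Cyp2b9, Cyp3a16, Cyp3a25, Cyp51, Dnajb9, Elovl5, Fads2, Fgb, Fmo2, G0s2, Gadd45a, Gadd45b, Gclc, Gls2, Glul, Gsta1, Gzma, Hamp, Hmga1, Hsd17b7, Kyat3, Maff, Mt1, Ngfr, Nr1i3, Nr4a1, Oat, Pdia4, Pdia6, Pdk4, Plin3, Pmaip1, Pnpla2, Rrm2, Sc5d, Scd2, Sdsl, Sparc, Spink1, Stab1, Trem2 and Vwf. With median centring (0.0539 to 0.354) they were Ahr, Apoa1, Asgr2, Calr, Cd2, Cyp3a16, Cyp51, Elovl5, Fads2, Gadd45a, Gadd45b, Gclc, Glul, Gsta4, Hsd17b7, Maff, Oat, Pdia4, Pdia6 and Sparc. With an offset of 10 (0.0515 to 0.0917) they were Acox2, Ahr, Apoa1, Calr, Cry2, Cyp3a25, Cyp51, Dnajb9, Elovl5, Fads2, Gadd45a, Gadd45b, Gls2, Glul, Hsd17b7, Pdia4, Pdia6, Plin3, Pnpla2 and Scd2. With no background correction Ahr, Calr, Cry2, Dnajb9, Fads2, Hsd17b7, Pdia4 and Plin3 did not pass (0.0520 to 0.0650), and on the single slide Acox2, Cry2, Cyp3a25, Dnajb9, Gadd45b, Maff and Pdia4 did not (0.0641 to 0.147). Single settings ended Dnajb9 and Hmga1 (mean over probes), Dnajb9 (strict filter), Cry2 (no filter), Gadd45b (5 separate arrays, also with slide as a block), Alb and Plin3 (mouse arrays alone) and Alb (swap averaged in). Aquantile left all ratios unchanged and so tests nothing.

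Lists that stopped passing: with 5 separate mouse arrays, p53 targets (0.0658, the same with slide as a block). With Feature Extraction log ratios and the series table alike, fatty acid and triglyceride synthesis (0.0740), pericentral (0.0795), periportal (0.0691 and 0.0692), p53 (0.0920 and 0.0921) and red blood cell (0.112). With median centring, pericentral (0.0659), oncofetal (0.0736) and red blood cell (0.0506). With mouse arrays alone, pericentral and red blood cell (both 0.108) and periportal (0.251), the last also with the swap averaged in (0.101). With an offset of 10, red blood cell (0.0599). On the single slide, glucose (0.0860), p53 (0.105) and red blood cell (0.0599). With the strict filter, fatty acid and triglyceride synthesis and red blood cell (both 0.0583).

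Lists that began to pass: AP-1 subunits with median centring (0.0331), the swap averaged in (0.0489), mouse arrays alone (0.0494) and no filter (0.0369). Cholesterol passed with the swap averaged in (0.0166), mouse arrays alone (0.0112) and on the single slide (0.0340), extracellular matrix with no filter (0.0394) and on the single slide (0.0448), and the respiratory chain with median centring (0.00397).

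Leaving out a mouse gave 4.59e-07 to 0.0682 for fatty acid and triglyceride synthesis, 0.0102 to 0.320 for cholesterol, 0.0309 to 0.118 for extracellular matrix, 0.0293 to 0.0702 for p53 and 0.00602 to 0.0717 for red blood cell markers.

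The correlations estimated for the 21 called lists ran from -0.0513 for oncofetal to 0.644 for neutrophil genes. That of acute phase genes, 0.0137, was near the preset value. A correlation above the preset one therefore does not by itself account for the lost calls of oncofetal and acute phase genes. What else ended them was not tested. With an estimated correlation 0 of 21 lists kept their call. The adjusted p was 0.442 for fatty acid oxidation, acute phase, cytokines, cholangiocyte, macrophage, T and NK cell, neutrophil, endothelial, periportal, interferon, male-biased and oncofetal genes, 0.494 for bile acid, glucose, xenobiotic, pericentral, cell cycle, p53, complement and red blood cell genes, and 0.714 for fatty acid and triglyceride synthesis. Fry, which asks only whether members move one way, passed 4 lists: fatty acid oxidation, acute phase, interferon, and B and plasma cell markers (0.0212), which camera did not call. Its adjusted p was 0.521 for fatty acid and triglyceride synthesis, 0.133 for bile acid and p53, 0.0707 for glucose, cell cycle and complement, 0.213 for xenobiotic, 0.0604 for cytokines, neutrophil and periportal, 0.112 for cholangiocyte, 0.0676 for macrophage and endothelial, 0.0579 for T and NK cell and male-biased, 0.142 for pericentral, 0.0531 for oncofetal and 0.168 for red blood cell genes.

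Signal limits what can be seen: at most 58.9% of probes were above background in a channel, and Fosl1, Il6, Gpc3 and Xist were among the list genes too dim to test.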

Other observations

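The genes named here beyond the planned rule were chosen after their values were seen; the list tests were planned.

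Matrix and stellate cell genes moved in both directions. Of 24 extracellular matrix genes, 7 rose and 2 fell, and 12 changed adjusted over the list alone (camera adjusted p = 0.0603, and 0.0309 without mouse 1 or 0.0457 without mouse 4). The basement membrane collagens Col4a2 (log2 0.56, SE 0.06) and Col4a1 (0.37, SE 0.07) and the collagen Col6a1 (0.49, SE 0.09) rose, while Tgfb1 (-0.42, SE 0.08) and Sparc (-0.39, adjusted p = 0.0200) fell. Among 11 stellate cell markers, Cygb (0.69, SE 0.06), Pdgfra (0.51, SE 0.06) and Pdgfrb (0.32, adjusted p = 0.0202) rose, and Acta2, the smooth muscle actin of activated stellate cells (-0.84, SE 0.09), and Ngfr (-0.47, SE 0.09) fell. Adjusted over the list alone 5 changed, and the list did not pass (camera adjusted p = 0.855, median -0.03, mean 0.02).

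Glutathione and NRF2 genes also split. Of 26 tested, 5 rose and 3 fell, and 10 changed adjusted over the list alone (camera adjusted p = 0.855, with the direction of the test below 0 and a mean of 0.11). The glutathione transferase genes Gsta2 (log2 1.21, SE 0.15), Gsta1 (1.14, adjusted p = 0.0219), Gstp2 (0.94, SE 0.11) and Gstp1 (0.78, adjusted p = 0.00281) and the sulfiredoxin gene Srxn1 (0.67, SE 0.07, n = 3) were higher, and Hmox1 (-0.55, SE 0.07), Gsta4 (-0.36, adjusted p = 0.00980) and Gclc (-0.35, adjusted p = 0.0101) were lower. Gsta1 and Gsta2, like Gstp1 and Gstp2, are close paralogs whose probes may share signal, and Gsta1 did not pass with an intensity trend and robust variance (adjusted p = 0.146). Of 18 ER stress genes, Asns and Dnajb9 (0.42, adjusted p up to 0.0837 without mouse 1, 2 or 5) rose and 3 chaperone genes fell: Pdia6 (-0.37, SE 0.09), Calr (-0.30, SE 0.08) and Pdia4 (-0.26, SE 0.07). Each of these 3 falls no longer passed without some mice (adjusted p up to 0.0564 for Pdia6, 0.0761 for Calr and 0.0817 for Pdia4). Adjusted over the list alone 6 changed, and the ER stress list did not pass (camera adjusted p = 0.952, direction below 0, median 0.01, mean 0.28, the mean carried by Asns at 5.42).

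Complement and coagulation genes fell in 8 of 28 cases and rose in 1, C6, and 9 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000908, adjusted p = 0.494 with an estimated correlation). F11 (log2 -0.84, SE 0.10), C8a (-0.74, SE 0.10) and the mannose-binding lectin gene Mbl1 (-0.56, SE 0.07) were among those that were lower. Of 15 immediate early genes, the phosphatase gene Dusp1 rose (0.72, SE 0.10), Nr4a1 (-1.05, SE 0.17), Atf3 and Gadd45b (-0.29, SE 0.08, adjusted p up to 0.0803 without mouse 1, 2, 4 or 5) fell, and 5 changed adjusted over the list alone (camera adjusted p = 0.460). Of 7 B and plasma cell markers, Cd79b (-0.72, SE 0.08) and Ms4a1 (-0.41, SE 0.07) fell, and 3 changed adjusted over the list alone (camera adjusted p = 0.716, median 0.11, mean -0.02).

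Among 17 circadian clock genes, Cry2 passed at the threshold (log2 0.26, SE 0.07, adjusted p up to 0.0809 without mouse 1, 3 or 5), against 0 adjusted over the list alone (camera adjusted p = 0.855). In the respiratory chain 0 of 26 genes passed, also adjusted over the list alone (camera adjusted p = 0.947), with Cox7a2 at 0.13 (adjusted p = 0.232) and Sdhd at -0.12 (adjusted p = 0.24). Of 5 pancreatic acinar genes 0 passed, also adjusted over the list alone (camera adjusted p = 0.141), with Cel at 0.17 (adjusted p = 0.0961) and Cela2a at 0.18 (adjusted p = 0.143), beside a log2 ratio of 3.52 for Cela1. Of the adipose markers only Cfd was tested and fell, also adjusted over the list alone. Adipoq, Plin1, Retn and Lep were well above background on 0 arrays in the Fra-1hep channel. In the wild-type channel this was so on 1 array for Adipoq and Retn and on 0 for Plin1 and Lep. These genes were therefore too dim to compare between the groups.

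The genes that changed most differed in how evenly they did so in the 4 Fra-1hep samples. The SD of the log2 ratio was 0.04 for Lrtm2, 0.11 for Dmbt1, 0.18 for Inava, 0.22 for Cela1 and 0.24 for Gipc2, against 1.02 for Igfbp1, 1.13 for S100a9, 1.36 for Hamp, 1.40 for Kyat3 and 1.59 for Mpo. The wild-type signal of Lrtm2 was not well above background on most arrays, so its evenness is that of a ratio to a dim signal.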
